A study of Homo sapiens with 9 samples.

How the data were processed

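The series holds chromatin immunoprecipitation with sequencing (ChIP-seq) for HIF-1α in SK-N-BE(2), a human neuroblastoma cell line with amplified MYCN. Per the labels, cells were kept for 48 hours at 21% oxygen (normoxia) or 1% oxygen (hypoxia), with 3 libraries in each group and 3 input libraries, all from 21% oxygen. The 6 HIF-1α libraries have 1 peak list each, made per sample rather than on pooled samples. The input libraries enter only through the control signal in those lists, and no input from cells at 1% oxygen was used here. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

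Per the submitters' processing notes, the tools were BWA 0.7.17 and MACS2 and the genome build was hg19. The MACS2 version, its settings, and any filter on duplicate reads are not given in the sources used here. The deposited lists are narrowPeak tables, whose score column held 10 times the −log10 q value cut to a whole number in all 16463 lines. The deposited fold column is a ratio of reads at the summit to the local background, and the deposited −log10 p and −log10 q values are the authors' peak caller's own. Fold, p and q describe a peak within its list and ranked or filtered peaks there; fold and p also served to recover reads and local background, as described below. The lowest −log10 q lay between 1.30 and 1.65 in the 6 lists. The lowest −log10 p was 6.18, 7.15 and 6.37 in normoxia 1, 2 and 3 and 5.28, 4.43 and 4.23 in hypoxia 1, 2 and 3, so a call needed a smaller p in the short lists.

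Each list can hold several summits of 1 interval. Intervals with the same start and end were counted once, with the values of the summit of smallest p, and positions were written 1-based. Comparisons used chromosomes 1 to 22, X and Y, except for 1 alternative count on all contigs. Intervals of the 6 lists that shared at least 1 bp were joined into regions by a script that took the place of the planned bedtools merge. A region called in at least 2 of the 3 lists of a group is named replicated.

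The total number of reads is not in the lists, so the reads behind each summit were recovered from the fold and p columns. A whole number of reads and a local background were sought for which the reads plus 1 over the background plus 1 gave the fold, and the Poisson tail gave the −log10 p within 0.001. All 16463 summits came out whole (100%). On 500 simulated summits the same code recovered the planted reads in 100%, and it took 0.41% of summits with fractional reads for whole. In simulated lists with 2020 planted regions of at least 2 lists, 2020 were found. The smallest local background in a list was taken as its genome-wide background, and the shortest interval as its fragment extension, since MACS2 reports no interval shorter than that by default. The steps between background values, searched from 35 to 400 bp, gave the same extension in all 6 lists, 46, 47 and 47 bp in normoxia 1, 2 and 3 and 48, 155 and 167 bp in hypoxia 1, 2 and 3.

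The genome-wide background divided by the extension served as the depth of a library. It was 6.69, 6.02 and 6.26 reads per kb in normoxia 1, 2 and 3 and 6.62, 5.94 and 5.31 reads per kb in hypoxia 1, 2 and 3. The same steps gave the depth of the control behind each list, 7.85, 7.40 and 7.09 reads per kb for number 1, 2 and 3 in both groups. Control depths differed by at most 0.00694% between lists of the same number and by 4.15% to 10.8% between lists of different numbers, as a control shared between same-numbered lists would give. At these depths a median of 9 to 24 reads lay behind the summit of an interval, which limits the precision of any 1 interval.

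Interval counts and covered lengths were compared between 3 hypoxia and 3 normoxia lists by two-sided exact permutation tests of log2 values, whose smallest possible p is 0.1. Shares of intervals or regions have exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only and treat regions as independent. Overlap of lists was set against 100 random placements of each interval on its chromosome, whose length was taken as the largest interval end. The Jaccard index, the regions shared by 2 lists over the regions in either, was compared within and between groups over the 10 splits of the lists. The window from 14 to 18 Mb of chromosome 2 was fixed before the data were examined because it holds MYCN; the gene's chromosome was checked in a RefSeq gene table of GRCh38.p14, of which no coordinates were used. Alternatives fixed in the same way included stricter q and fold thresholds, other definitions of overlap such as summits within 150 bp, leaving out each library, a replicate block, and lists cut to the same length. Alternatives on the count of every summit row, interval length, a common p, fragment extension, local background and fold percentiles were added after the data were seen. A local background of at least 10 times the genome-wide value is called high.

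Regions named in the text followed a rule fixed with the other choices. It took the 10 regions called in all 3 hypoxia lists with the best mean percentile of fold within those lists. It also took up to 5 regions called in at least 2 normoxia lists. These were ordered by number of normoxia lists, then by mean percentile of fold within the normoxia lists. Regions outside the rule are said to have been chosen after their values were seen. Of the planned results, the share of peaks at promoters, the hypoxia response element at summits and the 11 gene lists need an hg19 sequence or annotation, which was not used here, and were not run. The rule's parts on gene names were dropped for the same reason, and regions carry coordinates without genes. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.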

Results

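HIF-1α is the oxygen-regulated subunit of the transcription factor HIF-1; it is degraded in oxygenated cells and accumulates when oxygen is low. Its binding sites were mapped by ChIP-seq in SK-N-BE(2) neuroblastoma cells after 48 hours at 21% oxygen (normoxia, 3 libraries) or 1% oxygen (hypoxia, 3 libraries), against input chromatin from 3 libraries at 21% oxygen. The comparison asks where on the genome HIF-1α is found in hypoxic cells and how much of that is found in normoxic cells. Libraries were of similar depth, with 6.02 to 6.69 background reads per kb in normoxia and 5.31 to 6.62 in hypoxia. All positions are 1-based on hg19.

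HIF-1α was called at far more places in hypoxic than in normoxic cells. The hypoxia libraries had 1408, 5833 and 7619 intervals, a mean of 4953 ± 3198 (SD, n = 3). The normoxia libraries had 75, 32 and 109 intervals, a mean of 72 ± 38.6 (SD, n = 3). The ratio of geometric means was 62.1, and the shortest hypoxia list was 12.9 times as long as the longest normoxia list. Intervals covered 1421 ± 1069 kb in hypoxia and 10.7 ± 7.87 kb in normoxia (SD, n = 3 each), a ratio of geometric means of 109. The median interval length per library was 205 ± 82 bp in hypoxia and 95.3 ± 15.9 bp in normoxia (SD, n = 3 each).

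For both measures all hypoxia values lay above all normoxia values, and the two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. The fragment extension behind the lists was 46 to 48 bp in the normoxia libraries and hypoxia 1, and 155 and 167 bp in hypoxia 2 and hypoxia 3. Among the 4 libraries with a short extension, hypoxia 1 had 22 times as many intervals as the geometric mean of the normoxia libraries. This rests on 1 hypoxia library, so no test can set it against the spread between hypoxia libraries. Both libraries with a long extension were hypoxic. Without hypoxia 1 the ratio of counts was 104 and that of covered length 221; without hypoxia 3 the ratio of covered length was 71.2.

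**Figure D1:**
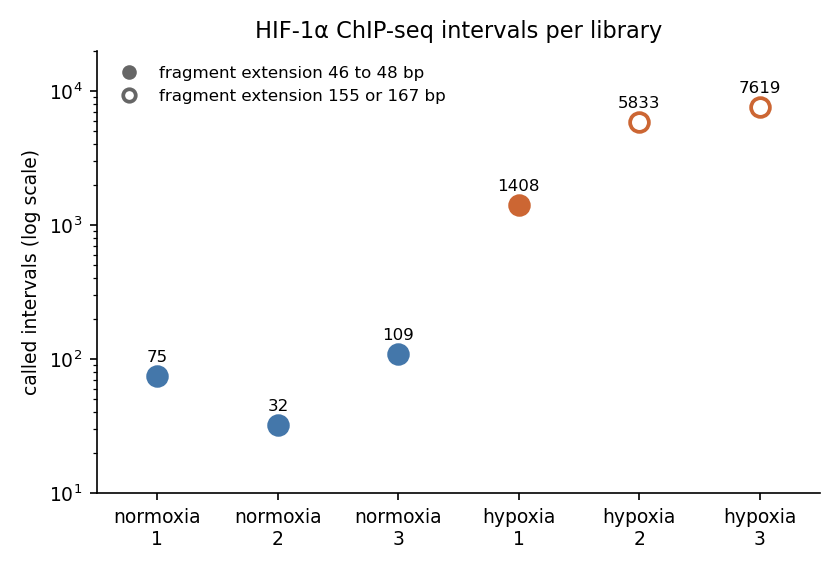
Called HIF-1α intervals per library on chromosomes 1 to 22, X and Y (y axis, log scale), normoxia in blue and hypoxia in orange, 1 point per library with its count. Filled points have a fragment extension of 46 to 48 bp and open points of 155 or 167 bp; the 3 hypoxia libraries lie between 1408 and 7619 and the 3 normoxia libraries between 32 and 109.

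Binding sites recurred between hypoxia libraries. Joined over all lists, intervals formed 9395 regions with a call in at least 1 hypoxia library, of which 4136 (44%, exact 95% interval 43% to 45%) were called in at least 2 and 1085 (11.5%, 10.9% to 12.2%) in all 3. The counterpart in normoxia was 29 regions called in at least 2 libraries, of which 20 were called in all 3. Most replicated hypoxia regions, 2989 of 4136, came from hypoxia 2 and hypoxia 3 without a call in hypoxia 1. The number therefore rested on those libraries: with hypoxia 2 left out 1134 regions were called in both remaining lists, and with hypoxia 3 left out 1096.

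The region that ranked first by fold within the 3 hypoxia lists was a 1008 bp stretch at chromosome 6: 44050244 to 44051251. The authors' fold over background there was 35.3, 93.4 and 135 in hypoxia 1, 2 and 3, and no normoxia list had a call. Next came chromosome 14: 34407289 to 34408153, with folds of 34.6, 81.6 and 96, and chromosome 5: 148801751 to 148802692, with folds of 28.8, 84.5 and 105. The region at chromosome 11: 1999864 to 2001295 had the highest fold of the whole list in hypoxia 2 (107) and in hypoxia 3 (137), and the region at chromosome 2: 86667604 to 86668666 that in hypoxia 1 (46.5). The other 5 of the first 10 regions lay at chromosome 2: 75005297 to 75006330, chromosome 16: 20013090 to 20014160, chromosome 19: 34849923 to 34850743, chromosome 16: 30076386 to 30077277 and chromosome 1: 162851567 to 162852579. The summits of hypoxia 1, 2 and 3 in the first of the 10 fell at 44050709, 44050769 and 44050775.

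Replicate lists overlapped far more than randomly placed intervals. Of the hypoxia 1 intervals, 87.7% (exact 95% interval 85.9% to 89.4%) overlapped a hypoxia 2 interval and 91.1% (89.4% to 92.5%) a hypoxia 3 interval. Hypoxia 2 intervals overlapped hypoxia 3 in 70.9% (69.7% to 72%), and hypoxia 3 intervals overlapped hypoxia 2 in 53.9% (52.8% to 55%). Normoxia 2 intervals overlapped normoxia 3 in 84.4% (67.2% to 94.7%), whereas normoxia 1 intervals did so in 45.3% (33.8% to 57.3%). Longer lists overlapped shorter ones less: hypoxia 2 and hypoxia 3 intervals overlapped hypoxia 1 in 18.8% and 14.9%, and normoxia 3 intervals overlapped normoxia 1 in 24.8% and normoxia 2 in 21.1%. Normoxia 1 intervals overlapped normoxia 2 in 25.3% and hypoxia 1 in 73.3%. For the pairs of hypoxia lists, the highest share in 100 random placements was 0.426%. The mean Jaccard index was 0.246 within groups and 0.0174 between groups, a difference of 0.229 (exact permutation p = 0.1 over 10 splits, the smallest possible). The lengths of the lists keep every index between groups below the lowest index within groups (0.147), so this test says nothing of the groups. With the best 32 intervals of every list the difference was 0.348 (exact permutation p = 0.1 over 10 splits, the smallest possible). These 32 are the whole normoxia 2 list but a small top part of each hypoxia list, so list lengths still enter.

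Nearly all replicated hypoxia regions lacked a normoxia call. Of 4136 regions, 4043 (97.8%, exact 95% interval 97.3% to 98.2%) overlapped no interval of any normoxia list and 93 overlapped at least 1. The normoxia lists formed only 138 regions in all, so most of the 4136 had to lack a normoxia call wherever these lay. A normoxia call was present at 77 of the 1085 regions called in all 3 hypoxia libraries (7.1%, 5.64% to 8.79%) and at 16 of the 3051 called in exactly 2 (0.524%, 0.3% to 0.85%). Among the regions called in all 3, ranked by fold, a normoxia call stood at 6 of the first 10, 22 of the first 50, 30 of the first 100 and 40 of the first 200. These counts rested on normoxia 3: a call in normoxia 1 or normoxia 2 stood at 0, 5, 6 and 11 of them. Without normoxia 3, 34 of the 4136 regions had a normoxia call, 32 of them called in all 3 hypoxia libraries, and 99.2% had none. A missing call is not absence of binding. At the hypoxia 1 intervals that normoxia 1, 2 or 3 did not call, a median of 7 reads would have been needed for a call at the depth and p of that normoxia list. The hypoxia 1 reads, scaled to that depth, reached the number needed at 85.2%, 61.8% and 69.2% of these intervals and 2 times that number at 19.5%, 12.2% and 14.2%. Below the first mark a signal as strong as in hypoxia 1 would not have been called, and below the second mark a signal 0.5 times as strong.

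The sites called in normoxia were mostly hypoxia sites. All 29 replicated normoxia regions were called in at least 2 hypoxia libraries and 28 in all 3. Local background was high at 3 of the 29. The first 5 by the rule were chromosome 5: 175874944 to 175875425, chromosome 4: 186316992 to 186318319, chromosome 9: 6715916 to 6716732, chromosome 17: 80415801 to 80416704 and chromosome 15: 93351931 to 93352811, each called in all 6 libraries. At the chromosome 17 region the authors' fold was 6.66, 15.6 and 31.9 in normoxia 1, 2 and 3, and 17.9, 61.9 and 91.2 in hypoxia 1, 2 and 3. At the chromosome 5 region it was 10.3, 12.7 and 9.41 in normoxia and 14.4, 25.5 and 30 in hypoxia. Its summit reads without depth correction were 18, 22 and 25 in normoxia 1, 2 and 3 and 21 in hypoxia 1. Those of the chromosome 17 region were 17, 26 and 59 in normoxia 1, 2 and 3 and 47 in hypoxia 1. Folds of lists with different extensions are not on 1 scale, so they describe a region within its list.

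Summit reads could be set side by side among the 4 libraries with a short extension. At regions of low background called in both lists, the depth-corrected ratio of hypoxia 1 to normoxia 1 reads had a median of 2.2 (quartiles 1.72 and 2.72) and was above 1 at 23 of 24 regions. Against normoxia 2 the median was 1.94 (1.52 and 2.36), above 1 at 20 of 22 regions, and against normoxia 3 it was 1.6 (1.12 and 2.77), above 1 at 60 of 73. At the 20 high-background regions shared with normoxia 1 the median was 1.07 (0.984 and 1.19), above 1 at 13. These ratios compare single libraries, regions are not replicates, and a region enters only if both lists called it.

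**Figure D2:**
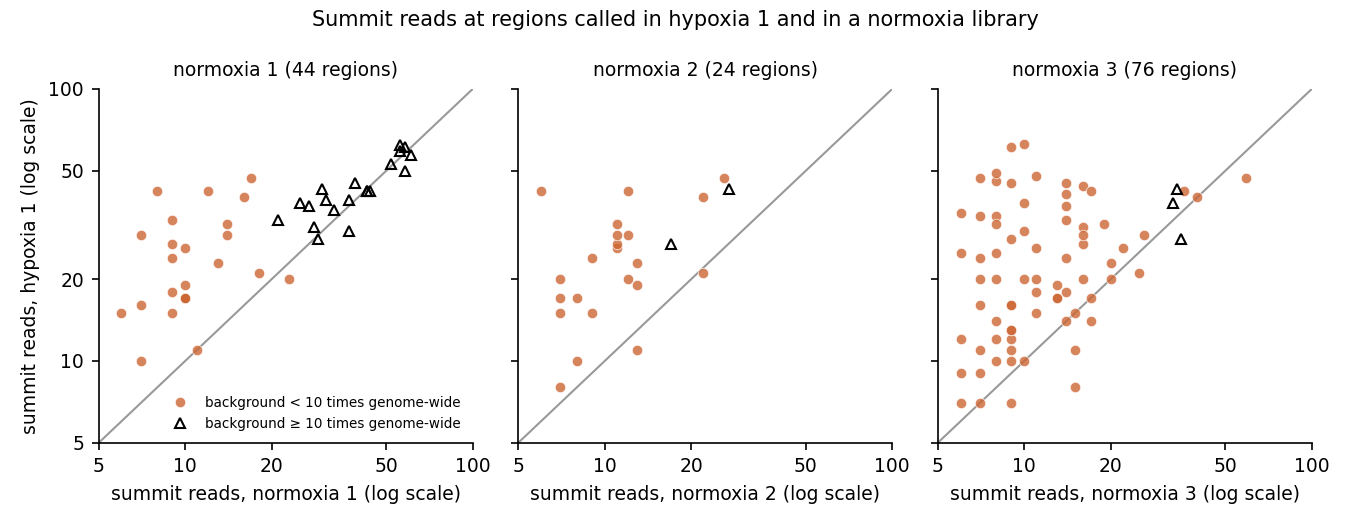
Reads at the summit in hypoxia 1 (y axis, log scale) against reads at the summit in normoxia 1, 2 and 3 (x axes, log scale), 1 point per region called in both libraries and without depth correction; the grey line marks equal reads. Orange circles are regions of low background, where hypoxia 1 was higher after depth correction at 23 of 24, 20 of 22 and 60 of 73 regions; black triangles are regions of high background, which lie near the line in normoxia 1.

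Outside the 2p24 window, high-background calls were most frequent in library 1 of both groups, with 40, 2 and 7 in normoxia 1, 2 and 3 and 83, 9 and 19 in hypoxia 1, 2 and 3. Of the 75 normoxia 1 intervals, 40 (53.3%, exact 95% interval 41.4% to 65%) had a local background at least 10 times the genome-wide value, against 2 of 32 in normoxia 2 and 8 of 109 in normoxia 3. Of the remaining low-background intervals, 33 of 35, 28 of 30 and 94 of 101 in normoxia 1, 2 and 3 fell in a replicated hypoxia region. In total 25 of 138 normoxia regions had no call in any hypoxia library.

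At 2p24, the chromosome band of MYCN, hypoxia 2 and hypoxia 3 had dense calls of low fold. The window from 14 to 18 Mb of chromosome 2 is 0.129% of the summed chromosome lengths. It held 45 of 5833 intervals in hypoxia 2 (0.771%, exact 95% interval 0.563% to 1.03%) and 84 of 7619 in hypoxia 3 (1.1%, 0.88% to 1.36%). Hypoxia 1 had 2 intervals there (0.142%, 0.0172% to 0.512%), normoxia 3 had 1 (0.917%, 0.0232% to 5.01%), and normoxia 1 and normoxia 2 had 0, with upper bounds of 4.8% and 10.9%. In hypoxia 2, 36 of the intervals lay between 16079682 and 16575607, with a median fold of 1.65 and a local background of 153 times the genome-wide value. In hypoxia 3, 77 lay between 16076540 and 16594865, with a median fold of 1.52 and a local background of 149 times that value. Elsewhere in the genome the median fold was 6.53 and 6.15 in these lists.

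Mean shares in the window were 0.672% ± 0.488 in hypoxia and 0.306% ± 0.53 in normoxia (SD, n = 3 each; exact permutation p = 0.5), a difference within the spread between libraries. That difference of 0.366 percentage points was 0.631 without hypoxia 1, 0.316 without hypoxia 2, 0.151 without hypoxia 3, 0.213 without normoxia 1 or normoxia 2 and 0.672 without normoxia 3. A region outside the dense part, at chromosome 2: 15982533 to 15983540 and chosen after its values were seen, was called in all 3 hypoxia lists with folds of 7.87, 36.9 and 38.2 and in no normoxia list.

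**Figure D3:**
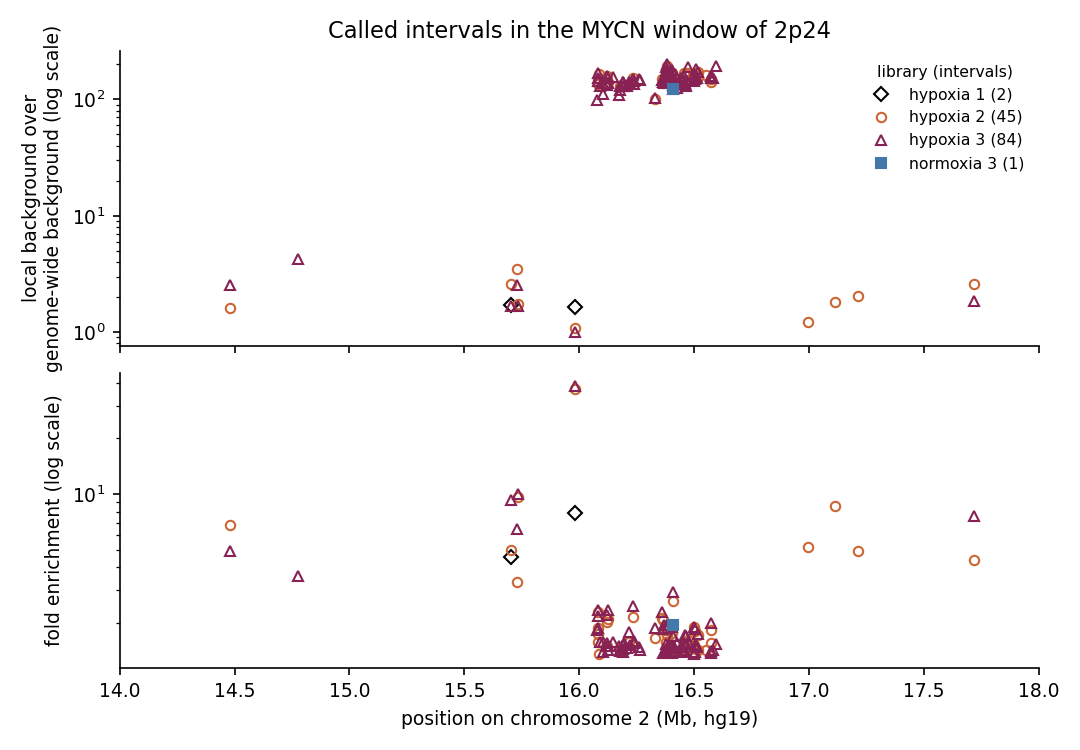
Called intervals in the window of chromosome 2 from 14 to 18 Mb (x axis, position on hg19), with the local background over the genome-wide background (upper panel, log scale) and the fold enrichment (lower panel, log scale); each symbol is 1 interval of the library in the key. The dense group between 16076540 and 16594865 combines a median background of 153 times the genome-wide value and a median fold of 1.65 in hypoxia 2 with 149 times and 1.52 in hypoxia 3.

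Replicated hypoxia regions were spread unevenly over the chromosomes. Their density was 35.5 per 10 Mb on chromosome 19 and 28.1 on chromosome 17, both known as gene-dense, followed by 20.9 on chromosome 22 and 20.1 on chromosome 11. Among chromosomes 1 to 22 and X it was lowest on chromosome 18 with 2.97 and on the X chromosome with 4.25, followed by 7.66 on chromosome 13 and 7.9 on chromosome 4. On chromosome 18 the local background equalled the genome-wide value at 87.5%, 77.1% and 88.9% of the intervals in hypoxia 1, 2 and 3, and on the X chromosome at 71%, 85.5% and 82.7%. On chromosome 10, with 17.1 regions per 10 Mb, it did so at 11.1%, 25.9% and 82.7%. On the remaining numbered chromosomes this share was at most 31.6%, 45.2% and 50.7% in the 3 lists. Among these it was 16.7%, 45.2% and 44.7% on chromosome 19 and 8.25%, 13.2% and 13.6% on chromosome 17. No test was run on these densities, and gene density was not measured.

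**Figure D4:**
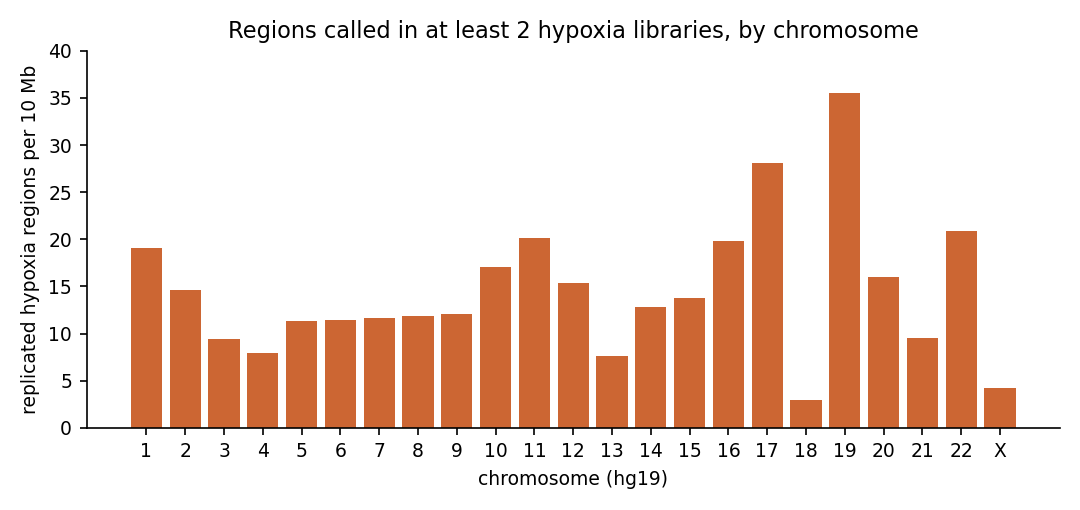
Regions called in at least 2 hypoxia libraries per 10 Mb (bars, y axis from 0) on chromosomes 1 to 22 and X of hg19 (x axis), with chromosome length taken as the largest interval end. Chromosome 19 has the highest bar with 35.5 and chromosome 18 the lowest with 2.97.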

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

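Outside the chromosomes compared, hypoxia libraries had more calls on unplaced, randomly placed and alternate contigs than normoxia libraries. Hypoxia 1, 2 and 3 had 56, 28 and 47 such intervals, while the highest normoxia library had 5. As a share of all intervals of a list the order was different: 3.83%, 0.478% and 0.613% in hypoxia 1, 2 and 3, and 6.25%, 0% and 0.909% in normoxia 1, 2 and 3. In hypoxia 1, 38 of the 56 lay on a single unplaced contig with a median local background of 118 times the genome-wide value and a median fold of 1.9. These contigs entered only 1 alternative count of intervals, with a ratio of geometric means of 61.6, and no explanation was tested for them. Groups of 3 libraries are too small for a test of single outlying libraries.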

How the results depend on the processing

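The alternatives on the count of every summit row, interval length, a common p, fragment extension and local background, and all those on fold percentiles, were chosen after the data were seen. The ratio of interval counts stayed above 1 under all 16 alternatives run and that of covered length under all 9, with p never below 0.1, the smallest this design allows, so these tests say nothing of stability. The ratio of counts was 171 with only intervals of at least 167 bp, 55.6 at 1 common p and 81.6 without high background. It lay between 43.9 and 104 with 1 library left out, and that of covered length between 71.2 and 221. Replicated hypoxia regions numbered 2387 at a fold of at least 6 and 1085 when all 3 hypoxia lists had to call them, fewer by construction, and between 1096 and 4073 with 1 hypoxia library left out. The share of hypoxia regions without a normoxia call was 98.3% at −log10 q of at least 5, 97.2% at a fold of at least 6, 99.1% with reciprocal overlap of at least 50%, and 92.9% for regions of all 3 hypoxia lists; with 1 library left out it lay between 92.9% and 99.2%. The normoxia lists are so short that this share is high by construction under each alternative. The cause of its shifts was not tested. The Jaccard difference, main value 0.229, ran from 0.119 with reciprocal overlap to 0.348 with the best 32 intervals of each list; list lengths fix the sign of the main value. The excess of hypoxia over normoxia in the 2p24 window was 0.133 percentage points without high background, 0.124 at a fold of at least 6 and 0.546 at −log10 q of at least 5 (exact permutation p = 0.1 each); all normoxia shares were 0 there, which fixes the sign. As a replicate block, same-numbered libraries gave ratios of 62.1 and 109 (exact sign-flip permutation p = 0.25 each). In the 2p24 window they gave 0.366 percentage points (exact sign-flip permutation p = 0.25). These values equal the main ones by construction, and this p is the smallest that 3 pairs allow. The block therefore says nothing of stability. Deviations of same-numbered libraries from their group means correlated at −0.0126 to 0.0835 over regions, and 3 of 6 libraries correlated best with their own number. Normoxia lists had calls at only 138 of the 9420 regions, so these correlations cannot decide whether the numbers pair the libraries. The main tests did not pair them, since the labels give only numbers. Same-numbered lists had controls of the same depth, and high-background calls outside 2p24 were most frequent in library 1 of both groups. Pairing therefore stays open. The promoter, sequence motif and gene list alternatives were not run, since they need an hg19 sequence or annotation. Depth limits single intervals, whose median summit had 9 to 24 reads in the 6 lists.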

Other observations

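Here, the tests of library depth, fragment extension, a common p, DNA copies, recurrence at 2p24, local background and random draws were chosen after the results they bear on had been seen.

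Replicated hypoxia regions clustered at some megabases, listed here after their values were seen. After the MYCN segment, with 29 regions from 16 to 17 Mb of chromosome 2, the densest were 18 to 19 Mb of chromosome 19 with 17 regions, 101 to 102 Mb of chromosome 14 and 85 to 86 Mb of chromosome 16 with 14 each, and 68 to 69 Mb of chromosome 11 and 128 to 129 Mb of chromosome 3 with 13 each. In the last 5 of these the median local background in hypoxia 3 was 1.13, 1.69, 1.48, 1.83 and 1.26 times the genome-wide value, against 154 times in the chromosome 2 segment.

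Of the regions called in normoxia, 20 were called in all 3 libraries and 4 in normoxia 2 alone. Regions called in normoxia 3 alone numbered 67, of which 64 were called in hypoxia, with a median fold percentile of 96.6 in the hypoxia 3 list and 97.6 in the hypoxia 2 list. Regions called in normoxia 1 alone numbered 38, with a median background of 38.7 times the genome-wide value, and 18 of them were called in hypoxia, all 18 in hypoxia 1 and 3 in hypoxia 2 or hypoxia 3. Their median fold percentiles were 2.27, 1.01 and 2.23 in hypoxia 1, 2 and 3. Of the 10 first hypoxia regions, 6 were called in normoxia 3 and 0 in normoxia 1 or normoxia 2.

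Chromosomes 8 and 10 were chosen after their values were seen, from a comparison of hypoxia 2 and hypoxia 3 counts on each of 24 chromosomes. Over the genome hypoxia 3 had 1.31 times as many regions as hypoxia 2 (7586 and 5773). On chromosome 10 it had 553 against 291 and on chromosome 8 it had 245 against 290. These values compare 2 libraries of 1 group, and the spread between libraries was not tested. The local background equalled the genome-wide value at 82.7% of the chromosome 10 intervals in hypoxia 3 and 25.9% in hypoxia 2, and at 6.45% of the chromosome 8 intervals in hypoxia 3 and 17.2% in hypoxia 2. A control with fewer reads on chromosome 10 would raise the count of hypoxia 3 there and the density of replicated regions; the inputs were not analysed here.

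The longer lists in hypoxia were set against 3 technical explanations. Deeper libraries were not the cause, since mean background reads per kb in hypoxia were 0.942 times those in normoxia. The shorter fragment extension of the normoxia lists does not account for hypoxia 1, which has an equally short one and was 12.9 times as long as the longest normoxia list. For hypoxia 2 and hypoxia 3 extension and oxygen cannot be told apart: the shorter of them was 4.14 times as long as hypoxia 1, the only hypoxia list with a short extension. With 1 common p in all lists the shortest hypoxia list was still 10.5 times as long as the longest normoxia list, so the stricter p in short lists does not account for it either. For 1008 regions called in all 3 hypoxia and no normoxia lists, 1 of 10 splits of the lists gave as many, the real one. The highest other gave 11. Every other split has a normoxia list, of at most 109 intervals, on each side, so none could come near 1008. List lengths thus fix this outcome, which says nothing of the groups. Besides, 10 splits are too few for a share under 0.05. The difference in oxygen, the biological explanation that the design gives, stays open, and the efficiency of the pull-down per library was not tested. All inputs came from normoxic cells, so the hypoxia lists had no control from hypoxic cells. A difference in background between hypoxic and normoxic chromatin therefore cannot be told apart from binding here, and was not tested.

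The low-fold calls at 2p24 were set against extra DNA copies, which the cell line is known to carry at MYCN. The median local background of intervals in the window was 147 times the genome-wide value in hypoxia 2 and hypoxia 3. Amplified DNA would raise reads in library and control alike, so this value does not test what made the calls. A candidate explanation is that small excesses over a very high background pass the p threshold there, with folds near 1.5. High-background calls in the window numbered 36 and 77 in hypoxia 2 and hypoxia 3, the lists with a long extension. In the lists with a short extension they numbered 0, 0 and 1 in normoxia 1, 2 and 3 and 0 in hypoxia 1. Extra copies, common to all libraries of the line, would not alone give this split, whose cause was not tested. Without high-background intervals, hypoxia 2 and hypoxia 3 had 0.155% and 0.093% of their intervals in the window. Positions recurred: 33 of the 36 high-background intervals of hypoxia 2 overlapped one of hypoxia 3, against at most 9 in 100 random placements within the segment. The normoxia 3 call lay within the interval of highest fold there in hypoxia 2 and hypoxia 3 (2.62 and 2.94). HIF-1α binding within the segment stays open, as neither folds nor positions separate it from excesses that recur for another reason.

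Regions called in at least 2 normoxia libraries mostly coincided with strong hypoxia sites. High local background was not the cause for most of them, as their median background was 2.02 times the genome-wide value. It was high at 3 of the 29, at chromosome 5: 9965 to 11819 and chromosome 12: 95464 to 95837 and 133841459 to 133841980. These 3 had mean fold percentiles of 6.67, 14.4 and 20.2 in the hypoxia lists and were not strong hypoxia sites. The median fold percentile of the 29 in hypoxia 3 was 87.6, above the central 95% of random draws from all hypoxia 3 regions (32.5 to 67.4). These draws included regions of a single list, whereas 28 of the 29 regions were called in all 3 hypoxia lists. Hypoxia 3 regions also called in hypoxia 1 had a median percentile of 91.2, and the others 44.8. The draws from hypoxia 3 therefore cannot tell a preference for strong sites from recurrence between hypoxia lists. In hypoxia 2 the median percentile of the 29 was 84.7, while that of regions also called in hypoxia 1 was 88.2. In hypoxia 1 the median of 28 of them was 92.5, above the central 95% of draws (35.4 to 70). Only 110 of the 1257 hypoxia 1 regions lacked a call in another hypoxia list. Most regions drawn there thus recurred too, but this rests on 1 library. Whether these sites are pulled down independently of oxygen cannot be told apart from residual HIF-1α binding in normoxia. Averaged over the normoxia lists, the depth-corrected ratio of hypoxia 1 to normoxia reads had a median of 1.71 (quartiles 1.36 and 2.04). It was above 1 at 24 of 28 regions. The average joined normoxia lists with unlike reads, and all 29 regions were called in normoxia 3. At the first 5 by the rule, which ranked them by fold in normoxia, summit reads without depth correction were 25, 36, 20, 59 and 40 in normoxia 3. They were 18, 12, 13, 17 and 16 in normoxia 1 and 22, 12, 13, 26 and 22 in normoxia 2. In hypoxia 1 they were 21, 42, 23, 47 and 40. HIF-1α binding at 21% oxygen therefore stays open, and none of the 10 first hypoxia regions was among the 29. Lists of the same number appear to share a control, which could add to their overlap and was not tested.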
